A study of Homo sapiens with 11 samples.

How the data were processed

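Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map the glucocorticoid receptor (GR) and the ubiquitin-like modifiers SUMO-2 and SUMO-3 (one antibody, SUMO-2/3) in HEK293 cells, a human embryonic kidney cell line. Per the labels, isogenic lines were made with a site-specific recombination system (Flp-In), in which the transgene enters the genome at a prepared FRT site. One line expressed wild-type GR, another the SUMOylation-defective receptor GR3KR (here the 3KR line), and a control line (FRT) carried no GR transgene. Cells were kept in steroid-depleted medium for 72 h and treated with 100 nM dexamethasone, a synthetic glucocorticoid, for 1 h before ChIP.

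Of the 11 samples, 9 had a peak list: GR and SUMO-2/3 in duplicate in the wild-type and 3KR lines, and 1 GR library of the control line. The input and IgG libraries of the control line, named in the series design as controls, had no list and were not analysed here. Samples were grouped by their titles. Nothing in the labels says beyond "biological duplicates" whether the libraries came from separate cultures, and each line stands for 1 cell population, so differences between lines carry no measure of the spread between independently made lines.

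Per the submitters' processing notes, base calls came from CASAVA and reads were aligned with Bowtie 0.12.9 to hg19. The peak caller, its control and its settings are not given in the sources used here. Per the file headers, each deposited list gives for every peak a start, end, length, summit, tag count, a p column, a fold enrichment and a false discovery rate in percent. The tag counts the authors deposited are whole tags in the library's own peak and are not normalized. The fold column the authors deposited is a ratio to the peak caller's background. The p column is headed as −log10 of the p-value per the file headers, but its values reach 3233.06 and repeat the ceiling 3100, so it was treated as a score and used only to rank peaks. The deposited FDR is in percent. All listed peaks had more than 50 tags, a fold enrichment above 8 and an FDR under 10 percent, which was checked on each file.

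The 2 libraries of each group had identical start and end positions for every site, while tags, fold, FDR, length and summit differed. In all 4 duplicate groups, 0 sites were wider than either library's own peak, so each site was read as the stretch shared by a peak of both libraries, which no header states. The number of sites is therefore 1 value per group, and a peak seen in a single library of a duplicate group cannot be counted. The narrowest site was 2 bp wide. Positions are hg19, counted from 1, since length equals end minus start plus 1 in the control-line list.

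Total sequencing depth is not stated. The tags inside listed peaks summed to between 1127839 and 4696781 per duplicate library and to 208776 in the control line. Duplicates differed in strength: the median ratio of tags, library 2 over library 1, was 1.74 for wild-type GR, 0.889 for 3KR GR, 1.60 for wild-type SUMO-2/3 and 1.91 for 3KR SUMO-2/3. Spearman correlations of tags across the sites of a group, which are not independent replicates, were 0.801, 0.842, 0.871 and 0.841 in the same order. Fewer than 1 percent of sites had equal tag counts in both libraries, so none was a duplicate deposit.

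Sites of different lists were called overlapping when they shared at least 1 bp. Chance overlap came from 1000 circular shifts of the second list along each chromosome, by at least 1 Mb, with a one-sided permutation p whose smallest value is 0.001. The end of the last site served as the chromosome end. Shifts keep the number, width and spacing of sites but place them in closed chromatin and unmappable sequence too, so they bound chance placement only. Shares carry exact 95 percent Clopper-Pearson intervals over sites. Classes of sites were compared by two-sided Fisher's exact tests, 7 in one family with Benjamini-Hochberg adjustment (2 of them, retention by GR retention and the same retention test for 3KR sites, added after seeing the data), and by Mantel-Haenszel odds ratios within quintiles of fold enrichment (mean rank of both libraries). Sites are not independent replicates, and all intervals and p-values describe counting error within these lists. Fold enrichment was used to rank sites within a list and, in the scaling alternative alone, was rescaled between lines by its median ratio at shared sites, which treats the 2 lines' background as comparable. Because each list counts tags in its own peaks, a common set of regions with counts in every library was not used here, and no count model was fitted. The planned rank by peak score was made with the fold column, chosen over the p column after its ceiling was seen.

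The sites named in the text follow a rule set before the data were examined, the 10 best ranked sites of each class, with the fold column as the rank chosen afterwards, of which the first few are given. Tests planned against gene annotation (position relative to genes, 10 gene lists) and against sequence (a GR response element) were not run, because no hg19 annotation or sequence was used here, and the files name no genes. Alternatives were another overlap rule, only sites above the median fold in both libraries, equal list lengths and leaving out control-line sites. Added after seeing the data were chromosomes with even tag ratios, scaling to the weakest library of the other line (taken separately for tags and for fold), and stratification by chromosome or 10 Mb window. Also chosen after seeing the data were the test of SUMO-2/3 retention by GR retention, the test of SUMO-2/3 in exactly 1 line, the McNemar tests, the chromosome comparisons (chromosome 19 included), tag ratios, spacing and dense windows. The overlap and odds ratio code was tested on simulated data. With exact copies of 29.8 percent of wild-type GR sites added to a shifted 3KR list cleared of other overlaps, 29.8 percent were recovered. This checks the code alone, since exact copies overlap under every rule, and not how the rules treat sites with differing ends. A simulated stratified odds ratio of 1.5 over 12109 sites was estimated at 1.51. Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and statsmodels 0.14.6 were used.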

Results

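GR and SUMO-2/3 binding was mapped by ChIP-seq in HEK293 lines expressing wild-type GR or the SUMOylation-defective GR3KR, after 1 h of 100 nM dexamethasone. SUMO-2/3 are small protein modifiers that are conjugated to lysines of many chromatin proteins, GR among them. The design asks how the loss of GR SUMOylation changes where GR binds and where SUMO-2/3 lies. Lists held 11259 GR and 12109 SUMO-2/3 sites in the wild-type line, 18856 and 7784 in the 3KR line, and 1016 GR sites in the control line without a GR transgene. They covered 12.9 Mb and 16.6 Mb, 21.4 Mb and 10.2 Mb, and 1.59 Mb of the genome, in that order. Each duplicate group is represented by 1 list common to its 2 libraries. Differences between lines in the number of sites therefore have no replicate error and no test.

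The 3KR line had 1.67 times as many GR sites as the wild-type line, and the wild-type sites were largely contained in it. Of the 11259 wild-type GR sites, 10006 (88.9%, 95% interval 88.3 to 89.4) overlapped a 3KR site, and 1253 did not. Of the 18856 3KR sites, 10002 (53.0%) overlapped a wild-type site and 8854 did not. Chance placement gave 161 overlaps of wild-type with 3KR sites on average and 202 at most (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). The strongest shared sites lay on chromosome 1 from 157389137 to 157390645, chromosome 12 from 52519816 to 52521275 and chromosome 3 from 14419538 to 14421637. In the wild-type libraries 1 and 2, the chromosome 1 site had 1021 and 1234 tags and fold enrichments of 81.13 and 45.65. All 10 best shared sites carried SUMO-2/3 in both lines.

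Sites listed in a single line were the weaker ones of their own list. In the wild-type list, median fold enrichment was 16.5 and 14.0 in libraries 1 and 2 at shared sites, against 11.6 and 10.1 at wild-type-only sites. In the 3KR list it was 27.2 and 17.8 at shared sites and 15.0 and 10.5 at 3KR-only sites. The share of 3KR sites with a wild-type counterpart was 97.1% in the highest quintile of fold and 13.2% in the lowest. Among the exceptions with high rank, 3KR-only sites lay on chromosome 5 from 42502463 to 42503890 (rank 281 of its list, 514 and 543 tags) and chromosome 2 from 138828640 to 138830735 (rank 767). Wild-type-only sites of high rank lay on chromosome 2 from 558617 to 559519 (rank 1009, 158 and 242 tags) and chromosome 8 from 98144552 to 98145428 (rank 1229). The best ranked wild-type-only site, at 9542242 on chromosome 1 (rank 376), was a stretch of a few base pairs shared by both libraries.

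The number of 3KR-only sites was also counted with the 3KR signal lowered to that of the wild-type line. The weakest wild-type library was taken separately for each column, library 1 for tags and library 2 for fold. Scaling tags and fold of the 3KR libraries to these and applying the listing limits again left 11850 sites, 3244 of them 3KR-only. Scaling both columns to wild-type library 1 left 5362 3KR-only sites, and to library 2 3330. With tags alone scaled to the weakest library 6896 3KR-only sites were left, and with fold alone 3330.

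**Figure D1:**
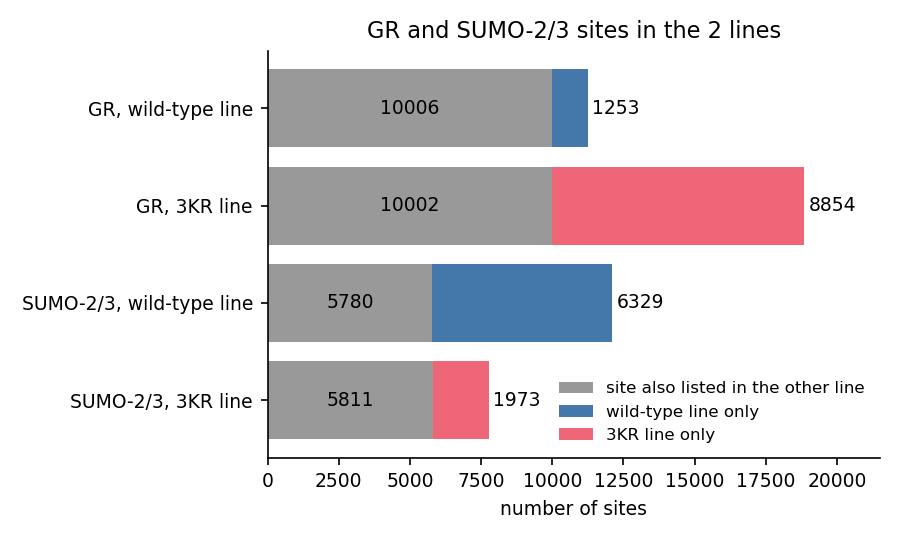
Number of GR and SUMO-2/3 sites per line (horizontal axis, count); grey parts are sites that overlap a site of the other line, coloured parts sites of one line only. GR has 8854 sites in the 3KR line only against 1253 in the wild-type line only, and SUMO-2/3 has 6329 in the wild-type line only against 1973.

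The GR antibody also gave peaks in the control line, which has no GR transgene. Of its 1016 sites, 833 (82.0%, 79.5 to 84.3) overlapped a wild-type GR site and 891 (87.7%, 85.5 to 89.7) a 3KR site. Seen from the other side, 843 wild-type sites (7.49%) and 904 3KR sites (4.79%) had a control-line site. These sites ranked high, with a median fold percentile from the top of 23.2 in the wild-type and 16.2 in the 3KR list. The 10 strongest control-line sites were GR sites in both lines. They included 3 sites on chromosome 11 between 114030263 and 114050827, of which the strongest (114049395 to 114050827) had 813 tags and a fold of 58.58. The control line had 1 library, so these values have no replicate check.

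For SUMO-2/3 the longer list was that of the wild-type line, with 1.56 times as many sites as listed in the 3KR line; this order turned when tags and fold were both scaled to the weakest 3KR library, and held when either was scaled alone. Of 12109 wild-type sites, 5780 (47.7%, 46.8 to 48.6) overlapped a 3KR site and 6329 did not. Of 7784 3KR sites, 5811 (74.7%, 73.7 to 75.6) overlapped a wild-type site and 1973 did not. Chance gave 102 overlaps of wild-type sites on average (permutation p = 0.001, the smallest possible). The strongest shared site lay on chromosome 16 from 85627955 to 85629314, with 529 and 641 tags and fold enrichments of 73.44 and 71.52 in wild-type libraries 1 and 2. It was a GR site in both lines, whereas the next, on chromosome 19 from 10526300 to 10528241, had no GR in either line. The strongest wild-type-only SUMO-2/3 site lay on chromosome 11 from 63437939 to 63439865 (rank 48, 434 and 732 tags), and the strongest 3KR-only site on chromosome 1 from 147825272 to 147826523 (rank 302).

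As for GR, unshared SUMO-2/3 sites were weak within their list: 86.8% of the highest quintile of wild-type sites by fold were found in the 3KR line, against 29.7% of quintile 4 and 509 of 2422 sites of the lowest. The number of wild-type-only sites left after scaling the wild-type signal to the 3KR line differed by the library scaled to. Scaling to 3KR library 1, whose peaks held fewer tags, left 2813 of the 6329 wild-type-only sites and a wild-type list of 7540 sites, against 7784 in the 3KR line, of which 3015 were then 3KR-only. Scaling to 3KR library 2 left 6206 wild-type-only sites and a list of 11970. With tags alone scaled to library 1 the wild-type list held 10096 sites, and with fold alone 8288.

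SUMO-2/3 lay at GR sites far more often than chance in both lines. In the wild-type line 4207 of 11259 GR sites (37.4%, 36.5 to 38.3) carried a SUMO-2/3 site, 33.8 times the chance mean. In the 3KR line 2940 of 18856 (15.6%, 15.1 to 16.1) did, 23.2 times the chance mean (permutation p = 0.001 in both, the smallest possible). The share followed GR strength: it fell from 86.1% of the highest quintile of wild-type GR sites by fold to 8.35% of the lowest, and from 47.1% to 3.08% in the 3KR line. With equal list lengths the shares were 26.1% in the wild-type and 23.2% in the 3KR line. Conversely, 34.3% of wild-type and 37.6% of 3KR SUMO-2/3 sites carried GR. Chromosome 19, a gene-dense chromosome singled out after its values were seen, held 7.35% of wild-type SUMO-2/3 sites but 1.60% of wild-type GR sites. There, 12.6% of wild-type SUMO-2/3 sites had GR, against 36.0% elsewhere, and 15.6% against 38.8% in the 3KR line. On chromosome 17, also looked at for its many SUMO-2/3 sites, the wild-type shares were 29.3% and 34.7%.

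Wild-type SUMO-2/3 sites that were not listed in the 3KR line occurred with and without GR. Of 4153 wild-type SUMO-2/3 sites with a wild-type GR site, 2012 (48.4%, 46.9 to 49.98) were found in the 3KR line. Of 7956 without GR, 3768 (47.4%, 46.3 to 48.5) were. The odds ratio of 1.04 (0.968 to 1.13) did not differ from 1 by Fisher's exact test (p = 0.258, adjusted 0.301), and the difference of 1.09 percentage points had an interval of -2.40 to 4.37 over resampled chromosomes. Sites with GR ranked higher by fold (median percentile from the top 45.4, against 52.5 without GR), and within quintiles of SUMO-2/3 fold retention was lower with GR (Mantel-Haenszel odds ratio 0.878, 0.807 to 0.956). In quintile 2, 53.9% of sites with GR and 64.2% of sites without GR were kept, and in quintile 1 84.3% and 88.4%. In quintile 5 the values were 22.8% and 20.3%, with overlapping intervals; the difference between quintiles was not tested. The direction depended on the settings: with region centres within 200 bp the odds ratio was 1.198, and 1.11 within quintiles, while above the median fold it was 0.655, and 0.484 within quintiles.

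**Figure D2:**
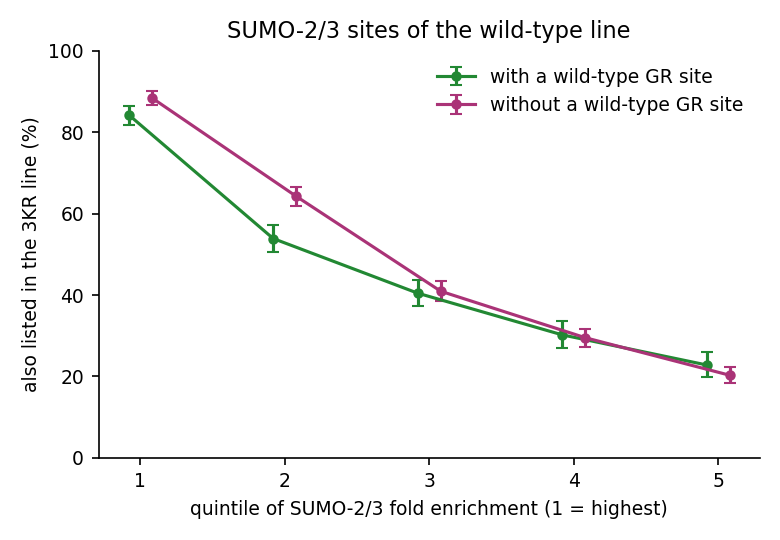
Share of wild-type SUMO-2/3 sites also listed in the 3KR line (vertical axis, percent) by quintile of fold enrichment (horizontal axis), for sites with and without a wild-type GR site; points are shares and bars exact 95% intervals over sites. Retention falls from 84.3% to 22.8% with GR and from 88.4% to 20.3% without GR, and the groups part in quintile 2 at 53.9% and 64.2%.

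SUMO-2/3 differed by class of GR site, and the difference in SUMO-2/3 between the lines depended on that class. At the 10006 shared GR sites, 40.1% had SUMO-2/3 in the wild-type line and 25.0% in the 3KR line. At the 1253 wild-type-only GR sites these shares were 15.3% and 1.84%. At the 8854 3KR-only GR sites the order was the other way round, with 3.82% in the wild-type line and 5.11% in the 3KR line (exact McNemar test over sites, p = 6.52e-08), although the 3KR list of SUMO-2/3 was the shorter one. Within the 3KR line, shared GR sites carried SUMO-2/3 more often than 3KR-only sites (odds ratio 6.15, 5.54 to 6.85), and within GR fold quintiles the ratio was 1.75 (1.52 to 2.01). The corresponding values for wild-type-only sites in the wild-type line were 3.70 (3.16 to 4.36) and, within quintiles, 1.21 (1.02 to 1.45).

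Wild-type SUMO-2/3 sites at GR were kept in 50.2% of 3970 cases where GR was also a site in the 3KR line, and in 11.5% of 183 cases where it was not (odds ratio 7.76, 4.88 to 12.9, Fisher's exact p = 1.87e-27). Within fold quintiles of both sites the odds ratio was 7.13, and under other settings it ranged from 1.87 with centres within 200 bp to 12.4 above the median fold. At 3KR GR sites with SUMO-2/3 in exactly 1 line, that line was the 3KR line in 278 of 442 cases (62.9%) at 3KR-only GR sites and in 489 of 2510 (19.5%) at shared ones (odds ratio 7.01, 5.61 to 8.76, Fisher's exact p = 2.84e-72). Within GR fold quintiles this odds ratio was 16.7 (12.2 to 22.8), and by chromosome 6.68 (5.23 to 8.52). Most changes of SUMO-2/3 at GR sites nevertheless lay where GR was listed in both lines. SUMO-2/3 was listed in the wild-type line alone at 2008 shared and 176 wild-type-only GR sites. It was listed in the 3KR line alone at 489 shared and 278 3KR-only GR sites. Of the 10 strongest wild-type-only GR sites, 10 carried SUMO-2/3 in the wild-type line and 1 in the 3KR line. Of the 10 strongest 3KR-only sites, 6 carried it in the 3KR line and 0 in the wild-type line. The site at 42502463 on chromosome 5 was one of the 6. Of the strongest wild-type-only sites, those at 9542242 on chromosome 1 and from 1995037 to 1995097 on chromosome 8 were narrow. Such sites can miss a site of the other line by position alone. Some lay on chromosomes 3, 8, 14 and 21, where tag ratios at shared sites leaned to the wild-type line for both antibodies. The others lay on chromosomes 1 and 2, where the ratios did not.

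**Figure D3:**
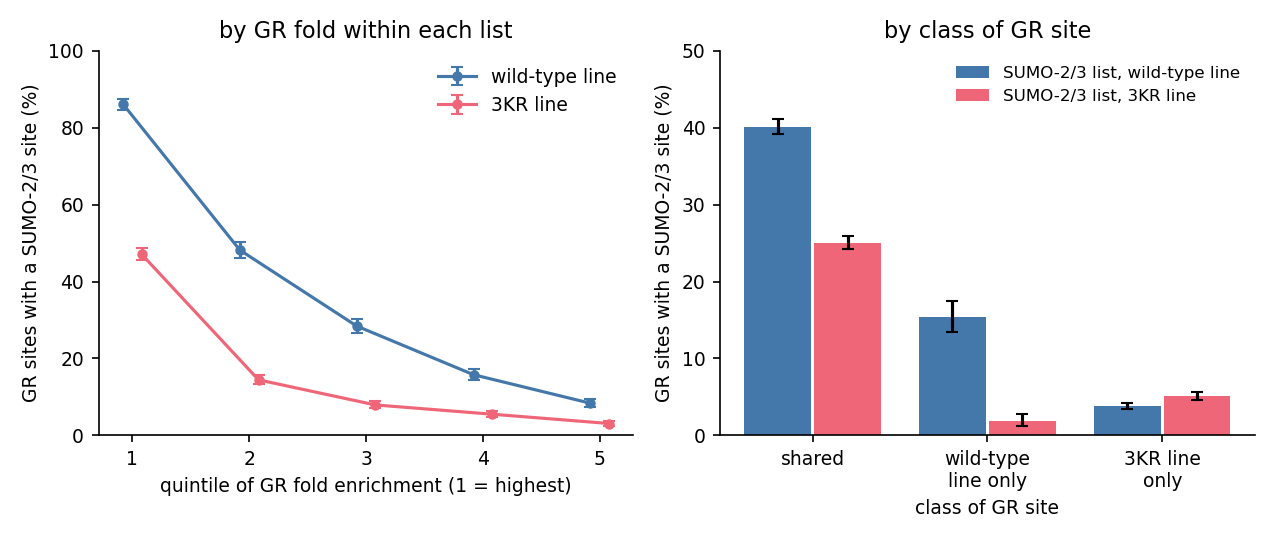
Share of GR sites with a SUMO-2/3 site (vertical axes, percent): left, by quintile of GR fold within each line's list (points, with SUMO-2/3 of the same line); right, by class of GR site for the SUMO-2/3 list of each line (bars). Error bars are exact 95% intervals over sites; the wild-type bar is higher at shared sites (40.1% against 25.0%) and the 3KR bar at 3KR-only sites (5.11% against 3.82%).

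The lines differed in how sites were spread over chromosomes, alike for both antibodies. Chromosome 3 held 9.25% of wild-type and 6.26% of 3KR GR sites, and 8.64% and 5.24% of SUMO-2/3 sites. Chromosome 14 held 4.99% and 3.45% of GR sites and 6.27% and 3.65% of SUMO-2/3 sites. Chromosome 18 went the other way, with 1.81% and 2.81% of GR sites and 0.743% and 2.33% of SUMO-2/3 sites. Over the 23 chromosomes, the log2 ratio of wild-type to 3KR shares for GR and for SUMO-2/3 had a Pearson r of 0.953 and a Spearman rho of 0.946 (permutation p = 1e-05 for both, the smallest that 100000 permutations can give, and 1e-05 adjusted over 3 relations). Without the 2 chromosomes farthest from the median r was 0.948. On the 8 chromosomes with even tag ratios between lines (1, 5, 10, 12, 15, 16, 22 and X, chosen after the data were seen), 306 wild-type-only and 3550 3KR-only GR sites remained of 3989 and 7216, and the odds ratio of SUMO-2/3 retention by GR retention was 4.34.

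**Figure D4:**
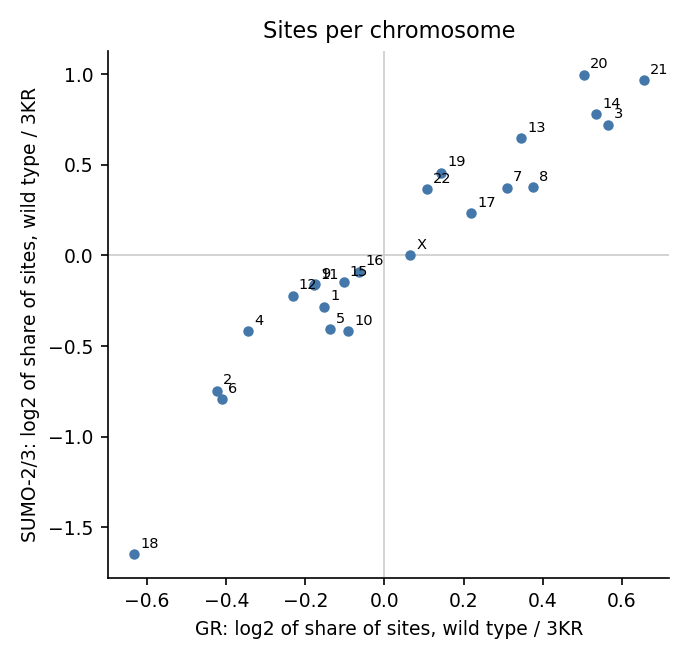
Log2 ratio of the share of sites on each chromosome in the wild-type over the 3KR line, for GR (horizontal axis) and SUMO-2/3 (vertical axis); each labelled point is 1 chromosome. Chromosomes 3, 14, 20 and 21 are high for both antibodies and chromosomes 2, 6 and 18 low for both (Pearson r 0.953).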

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

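All patterns in this part were noticed in the data. The tests of the chromosome pattern were chosen after like correlations over all shared sites had been seen, and the test within fold quintiles of both sites after its value was seen. The test by 10 Mb window was chosen before its value, but after the value by chromosome (6.33), was seen; both tests of the excess of 3KR sites came before their values, except that scaling to either library alone was added afterwards.

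Tag counts at shared sites, which the comparisons of lists do not use, differed between the lines by chromosome. Each site's ratio of wild-type to 3KR tags was averaged over the 4 pairs of libraries and centred on the genome median. Chromosome medians then spanned 1.35 log2 units for GR, from -0.61 on chromosome 18 to 0.74 on chromosome 21, and 1.14 log2 units for SUMO-2/3, from -0.56 on chromosome 18 to 0.58 on chromosome 21. Peak lengths differ between libraries, so the ratios are approximate. Bias of single libraries as the whole cause is argued against by the spread: the SD over chromosomes was 0.310 between lines for GR, 2.53 times the larger SD between duplicates (0.123), and 4.95 times for SUMO-2/3. Some chromosomes still depended on the pair of libraries. GR medians ran from -0.03 to 0.54 on chromosome 19 over the 4 pairs, but from -0.69 to -0.47 on chromosome 18. A bias common to both libraries of a line is not addressed by this spread. A change of GR binding by chromosome as the whole cause is also argued against, since SUMO-2/3 sites without GR followed GR sites without SUMO-2/3 over 23 chromosomes with a Pearson r of 0.959 (rho 0.9496, r 0.952 without the 2 farthest chromosomes) and a slope of 0.928. A difference in DNA copy number between the lines predicts that relation and stays open as a candidate explanation, untested against genomic DNA of each line. Within chromosomes, 206 windows of 10 Mb still correlated (r = 0.531, permutation p = 1e-05, the smallest possible). The permutation treats windows as independent, but neighbouring ones ran together. On chromosome 2, GR medians of the listed windows from 120 Mb on all lay between -0.70 and -0.53. The p-value therefore overstates the evidence.

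SUMO-2/3 sites changed together with GR sites between the lines in part, while most changes of SUMO-2/3 at GR sites were at shared GR sites. The line contrast in SUMO-2/3 differed between 3KR-only and shared GR sites, with an odds ratio of 7.01 by a test of the difference itself. Lost or gained DNA would remove or add both signals. Inside the same 10 Mb window the odds ratio of SUMO-2/3 retention by GR retention was 5.56 (3.46 to 8.92). This argues against copy number at that scale for the loss at wild-type sites. The gain at 3KR-only GR sites was stratified by chromosome (odds ratio 6.68, 5.23 to 8.52) but not by window. Joint loss of weak sites at the listing limits predicts no relation at equal strength. Within quintiles of wild-type fold of both sites the odds ratio was 7.13 (4.16 to 12.2). These quintiles do not equalise strength in the 3KR line or site width, so joint loss is argued against only at like wild-type fold. Without quintiles, the size depended on the overlap rule, at 3.51 with reciprocal overlap of 50% and 1.87 with centres within 200 bp. What stays open, untested, is whether the SUMO-2/3 at these sites is on GR, on proteins bound beside it, or background of strongly enriched chromatin. In the 3KR line the transgenic receptor is SUMOylation-defective per the labels, so SUMO-2/3 gained there is not ascribed to that receptor. GR not from the transgene was not excluded, since the control line also had GR sites. IgG and input were not analysed here. The biological difference of the design, the mutated receptor itself, cannot be separated from the difference between 2 single cell lines.

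The excess of 3KR GR sites was weighed in the same way. Copy number as the cause predicts a smaller excess on chromosomes with even tag ratios. The ratio of 3KR-only to wild-type-only sites there was 11.6, against 7.07 genome-wide, so the excess was not confined to uneven chromosomes. The rise itself is not read, because the choice of chromosomes also changed the wild-type-only share (306 of 3989 sites, against 1253 of 11259 genome-wide). Copy number within chromosomes was not covered. On chromosome 1, 10 Mb windows of GR sites without SUMO-2/3 had median log2 ratios from -0.449 to 0.152. Weaker signal in the wild-type libraries could account for part or much of the excess. Scaling tags to wild-type library 1 and fold to wild-type library 2, the weaker for each, left 36.6% of the 3KR-only sites. This was under the 50% set in advance as a sign of this cause. The combined reference is weaker than either real library, but wild-type library 2 alone, at 37.6%, was also under 50%. The combined reference left 3244 3KR-only against 2614 wild-type-only sites in lists of 11850 and 11259. Scaling to wild-type library 1 left 60.6% and a 3KR list of 14693 sites, to library 2 37.6%, and scaling tags alone to the weakest library left 77.9% (fold alone 37.6%), and because of this range the explanation is treated as open, a stricter reading adopted after these values were seen. As total depth is not stated, the strength of binding and the yield of the libraries cannot be told apart.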

How the results depend on the processing

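Of 115 values recomputed under alternatives, 81 kept their direction and side of the threshold or their size. For shares of overlapping sites only the one-sided permutation p was judged, which was 0.0099 throughout, the smallest that 100 shifts can give. The shares all count among the 81, although this p could hardly change. Their size moved all the same. The share of wild-type GR sites with a 3KR site, 88.9%, was 75.3% at equal list lengths. For SUMO-2/3 this share, 47.7%, was 62.7% after scaling. Merging touching peaks, also among the alternatives, changed no list, and its values count among the 81 too. No paired analysis was possible because, for counts of sites, both libraries of a group share 1 list of positions; tags do differ by library, and the difference in SUMO-2/3 tag ratio with against without GR was 0.13 and 0.10 log2 units in the pairs of equal replicate number; for the same reason sites of either library, or of 1 library alone, could not be counted. Leaving out a library changed only the ranks behind the retention odds ratio within fold quintiles, which ranged from 0.901 to 0.913 (0.878 with both). Tests against genes and motifs were not run. Even chromosomes, scaling to the weakest library and stratification by chromosome were chosen after seeing the data. Wild-type-only GR sites (1253) numbered 2749 with centres within 200 bp, 503 above the median fold, 2786 at equal list lengths, 306 on even chromosomes and 2614 after scaling; 3KR-only GR sites (8854) numbered 3574, 2810, 3550 and 3244 under the last 4. Wild-type-only SUMO-2/3 sites (6329) numbered 2575, 3056, 1886 and 2813 under those 4, and 3KR-only ones (1973) 3105 with centres within 200 bp, then 663, 3021, 811 and 3015. After scaling of tags and fold together to the weakest 3KR library, the order of the SUMO-2/3 lists turned (7540 wild-type against 7784 3KR sites), but not with tags alone (10096), fold alone (8288) or library 2 as the reference (11970), so weaker signal in the 3KR SUMO-2/3 libraries stays open for the difference in number. The lists above the median fold and on even chromosomes hold fewer sites by construction, and equal list lengths make the counts of unshared sites nearly equal in both lines. The share of wild-type GR sites with a control-line site (7.49%) was 6.52% with reciprocal overlap of 50%, 5.23% with centres and 8.23% above the median fold; for 3KR sites (4.79%) it was 4.29%, 3.30%, 5.78%, 7.44% at equal lengths, 4.31% on even chromosomes and 7.11% after scaling. The retention odds ratio with against without GR (1.04, p = 0.258) was the least settled: 1.198 with centres (p = 1.39e-05), 0.655 above the median fold (p = 4.36e-12), 0.858 at equal lengths (p = 0.00151), 0.963 without control-line sites (p = 0.35), 0.911 on even chromosomes (p = 0.161) and 0.797 after scaling (p = 3.3e-06), by Fisher's exact test; the cause was not tested. Within fold quintiles it turned to 1.11 with centres within 200 bp and was below 1 under the other alternatives, with its lowest value, 0.484, above the median fold. The retention odds ratio by GR retention (7.76) stayed above 1 throughout, from 1.87 with centres to 12.4 above the median fold. Depth is not stated, so sites under the listing limits of 50 tags and a fold of 8 are unlisted, not absent.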

Other observations

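The tests in this part were chosen after the lists had been seen, except those on tag ratios with against without GR and on retention stratified by chromosome, chosen before their values were seen. The densest 1 Mb windows of SUMO-2/3 sites differed in how many GR sites they held. The window of chromosome 6 from 27 to 28 Mb held 45 SUMO-2/3 sites in the wild-type and 54 in the 3KR line, with 0 and 2 GR sites, and the next window to 29 Mb held 43 and 43, with 1 and 6 GR sites. The window of chromosome 19 from 3 to 4 Mb had 43 SUMO-2/3 sites in the wild-type and 4 in the 3KR line, with 7 and 8 GR sites, and that of chromosome 17 from 80 to 81 Mb had 34 and 26, with 16 and 21 GR sites. The densest wild-type GR window, chromosome 8 from 37 to 38 Mb, held 31 GR and 36 SUMO-2/3 sites in the wild-type line, and the lists of the 3KR line held 24 and 14 there. Chromosome 1 from 232 to 233 Mb went the other way, with 9 wild-type and 33 3KR GR sites. The windows were picked for high counts in a list, which favours a lower count in the other line. Median log2 tag ratios in the surrounding 10 Mb leaned to the wild-type line for chromosomes 8 and 19 (GR 0.59 and 0.49, SUMO-2/3 0.55 and 0.63). They leaned to the 3KR line for chromosomes 6 and 1 (GR -0.57 and -0.10, SUMO-2/3 -0.68 and -0.43). The contrasts between lines are therefore not read as local changes.

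GR sites of a single line lay near shared GR sites more often than chance, yet mostly at a distance. Of 3KR-only sites, 17.3% lay within 10 kb of a shared GR site, against 5.77% after circular shifts (permutation p = 0.005, the smallest that 200 shifts can give), with a median distance of 59.0 kb. Of wild-type-only sites 25.5% did, against 6.13% after shifts (permutation p = 0.005). The share was lower for 3KR-only than for wild-type-only sites (odds ratio 0.612, 0.532 to 0.705, Fisher's exact p = 1.55e-11).

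A hypothesis was that the peak threshold hides a loss of SUMO-2/3 at GR sites in the 3KR line. At SUMO-2/3 sites shared by both lines, the wild-type to 3KR tag ratio, centred per chromosome, was compared between 2185 sites with GR and 3595 without. The difference was 0.13, 0.02, 0.19 and 0.10 log2 units in the 4 pairs of libraries, 0.188 at most, with a mean over pairs of 0.09 (0.05 to 0.15 over resampled chromosomes). The pairs reuse the same 4 libraries and are not independent, and for wild-type library 1 over 3KR library 2 the interval held 0 (-0.01 to 0.06). The size did not pass 0.1 in every pair, the limit set in advance, so the hypothesis stays open. GR tags at shared GR sites shifted by a like amount with against without SUMO-2/3 (0.09, 0.06 to 0.11). Whether copy number bears on retention with against without GR also stays open. The odds ratio stratified by chromosome was 1.01, inside the unstratified interval (0.968 to 1.13). This met the rule set in advance against the explanation. Its own interval, 0.934 to 1.09, reached beyond the unstratified one, a requirement added after the value was seen. Both intervals rest on the same sites and are of like width, so the added requirement could hardly be met and does not decide the question. By chromosome and fold quintile together the odds ratio was 0.7996 (0.731 to 0.875), against 0.878 (0.807 to 0.956) by fold quintile alone. On even chromosomes the odds ratio was 0.714 within fold quintiles and 0.911 without quintiles.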
